A study of Mus musculus with 60 samples.

How the data were processed

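Expression was measured in total RNA of mouse tissues on a custom Affymetrix array of glycan-related genes, with 60 arrays from 18 animals in 18 groups of line, genotype and tissue. The deposited values are log2 expression values that the authors made with robust multi-array averaging (RMA), per the labels, without a stated version and without a statement of whether all arrays were normalized together. The values lay between 2.113 and 14.069, none was missing, and array medians lay between 5.295 and 5.76. They were used as deposited, on the log2 scale, with no further normalization. For arrays the number of replicates limits the precision.

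Of 1246 probe sets, 963 were given a gene symbol through their RefSeq identifier and the supplied gene table (909 genes, 48 of them with several probe sets), and only these entered the tests and the adjustment. The other 283, most of them with identifiers of another gene track, have no symbol and were tested only in an alternative. Of the named probe sets, 217 carry a suffix that marks probes shared with other transcripts. A gene with several probe sets was represented by the probe set with the highest mean over all arrays, and a disagreement between probe sets is stated beside the gene.

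The animal was the replicate, so the 2 brain arrays of animal 9099 were averaged. Knockout and wild type were compared within each tissue with limma 3.58.1 in R 4.3.3 (linear model, moderated statistic, 2-sided p), with sex as a covariate except in testes, where all animals are male. The mean over the 4 tissues of a line, and the difference of the knockout effect between tissues (moderated F test), came from a fit of all knockout and wild-type arrays of the line with a sex term per tissue and the animal as a random block. The block correlation was -0.118 in the St6galnac2 line and 0.0734 in the B4galnt1/B4galnt2 line. C57 mice carry no sex label, so sex was no covariate there. Each wild-type tissue was compared with the mean of the other 3 tissues of its line. Sex was compared in kidney and mammary gland from the sex term of the knockout fit. P-values were adjusted by Benjamini-Hochberg within each comparison. A probe set was called at an adjusted p under 0.05, and in tissue comparisons also at a log2 difference of at least 1. Errors beside differences are standard errors and those beside group means are standard deviations.

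Of 47 gene lists, the 36 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, and adjusted within each comparison. Of the list calls, 59 were made with the preset correlation and 0 with a correlation estimated for each list, which was not estimated for means over tissues and their 3 calls. With every probe set counted 67 were made. Lists, comparisons, tests, covariates, alternatives and the choice of named genes were set before the data were examined. The targeted genes were named first in every comparison. In knockout, C57 and sex comparisons all called genes were named where 30 or fewer were called, and otherwise the 10 largest rises and 10 largest falls. Where fewer than 10 were called, genes with the smallest p were added up to 10. For the test of differences between tissues the 30 smallest p were named, together with Cxcr3, which was chosen after its value was seen. In tissue comparisons the 5 largest differences upward and the lowest 2 were named. For a described list its called members by smallest p, at most 4, or the member with the smallest p were named. A few genes that these rules name are left out of the text, and they stay in the counts.

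Each array was compared with its labelled tissue by Pearson correlation across the probe sets that represent a gene. The mean of the tissue means was subtracted first, and arrays of the same animal and tissue were left out of the means. Correlations between single arrays were taken after the mean over all arrays was subtracted. Correlations across probe sets are not correlations across replicates. The limit of 0.3 below which an array stands apart, and the alternatives without these 4 arrays and without animals N3740 and N3738, were chosen after the values were seen. A lymph node array of animal 9094, at 0.513 with its own tissue and 0.493 with mammary gland, stayed in. No array was relabelled.

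The same animals gave several tissues, which makes a real pairing. The deviations of an array from its group correlated, in the median, at 0.037 between tissues of the same DKO animal and -0.004 between animals, at 0.099 and -0.035 in WT animals of that line, at 0.002 and -0.011 in St6galnac2 KO, at -0.054 and 0.001 in WT animals of that line, and at -0.058 and 0.017 in C57.

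The procedure was tested on simulated data, built from the fitted means and residual spread of each comparison with random normal noise. In each, 200 of the 963 probe sets were changed 2-fold or 4-fold. Noise was drawn separately for each probe set, so shared deviations of whole arrays were absent. The shares recovered hold for that setting and may be higher than in the real arrays. The share of the 100 2-fold changes recovered was 87% in thyroid, 62% in lymph node, 68% in brain and 25% in intestine of the St6galnac2 line, and 74%, 96%, 78% and 100% in thymus, testes, mammary gland and kidney of the other line. For 4-fold changes the shares were 98%, 89%, 92%, 54%, 90%, 100%, 90% and 100%. A low count in intestine therefore says little.

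Alternatives were a second quantile normalization, centring of each array on its median, a trended and robust prior variance, and all probe sets of the array. Another excluded dim probe sets, whose highest group mean lay below the percentile 25 of all values (4.211). Further alternatives were no sex covariate, males only, all groups of a line in a single fit, and blocks on the animal or on neighbouring animal numbers. The last were either brain array of 9099 alone, an estimated correlation for lists, and leaving out each animal in turn. Other splits of the samples into groups of the same sizes were counted, at most 100 for each comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures. Overlaps between comparisons that share their control group were not computed.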

Results

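Messenger RNA of glycan-related genes was measured on 60 arrays from 18 mice, which fall into 18 groups of line, genotype and tissue. The first line is labelled a knockout of St6galnac2, which encodes an enzyme that adds sialic acid to N-acetylgalactosamine on proteins. The second line is a double knockout of B4galnt1 and B4galnt2, which encode enzymes that add N-acetylgalactosamine to glycolipids and to sialylated chains. In the St6galnac2 line, wild type (WT, +/+) and knockout (KO) mice gave 3 animals each for thyroid, lymph node and brain, and 3 WT and 2 KO animals for intestine. The WT brain group holds 4 arrays because animal 9099 gave 2. In the B4galnt1/B4galnt2 line, WT and double KO (DKO) groups held 3 and 5 animals for thymus, 3 and 3 for testes, 2 and 5 for mammary gland, and 4 and 5 for kidney. The 3 WT thymus animals and 3 of the 5 DKO ones were male, so with the sex term the thymus difference rests on these males. WT mammary gland held 1 male and 1 female. Brain and small intestine of 3 further C57 WT mice served as outside controls. The study used expression to choose tissues for glycan analysis, so the questions are where each gene is expressed and whether loss of the targeted genes alters the others. The number of arrays limits the precision.

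Loss of the targeted transcripts was looked for first on every array. St6galnac2, on chromosome 11, averaged 6.01 ± 0.24 (SD, n = 3) in KO thyroid and 5.73 ± 0.23 in WT thyroid. In lymph node it averaged 6.34 ± 0.28 in KO and 6.51 ± 0.33 in WT. The 3 KO brain arrays lay between 5.49 and 5.71, against 5.67 to 8.49 on the WT brain arrays, and KO intestine averaged 8.70 ± 0.07 (n = 2) against 7.73 ± 1.78 in WT (n = 3). The KO minus WT difference was 0.28 ± 0.16 (SE) in thyroid, -0.17 ± 0.26 in lymph node, -0.57 ± 0.41 in brain (-0.11 without animal 9099) and 0.82 ± 1.20 in intestine (-0.05 without it), none called by limma (adjusted p = 0.989, 0.845, 0.905 and 0.991). B4galnt1, on chromosome 10, and B4galnt2, on chromosome 11, differed little between DKO and WT kidney, at 5.63 against 5.64 and at 3.85 against 3.83. For B4galnt2 the WT kidney arrays read 3.58 to 4.05, below the percentile 25 of all values (4.211). The WT thymus array of N9700 read 3.71 for it. At so low a WT level a loss could hardly show, so equal B4galnt2 readings there check nothing about the genotype. In DKO thymus B4galnt1 lay between 4.73 and 5.23 on all 5 arrays, whereas the array labelled WT thymus of animal N9700 read 5.45 and the WT mean was 7.54. In testes B4galnt1 averaged 6.98 in DKO and 7.30 in WT, and B4galnt2 averaged 4.58 and 4.43. The WT testes arrays read 4.28 to 4.55 for B4galnt2, little above 4.211, so a loss could hardly show there either. In mammary gland the DKO arrays of N5895 and N5892 read 7.91 and 7.93 for B4galnt1, above both WT arrays (5.67 and 6.38). The other DKO arrays read 4.83 to 6.83. For B4galnt2 the same DKO arrays read 8.53 and 8.21 and the others 3.74 to 4.39, against 3.93 and 8.09 in WT. The position of these probe sets relative to the targeted parts of the genes is not known, and a probe set outside the targeted part checks nothing about the genotype.

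**Figure D1:**
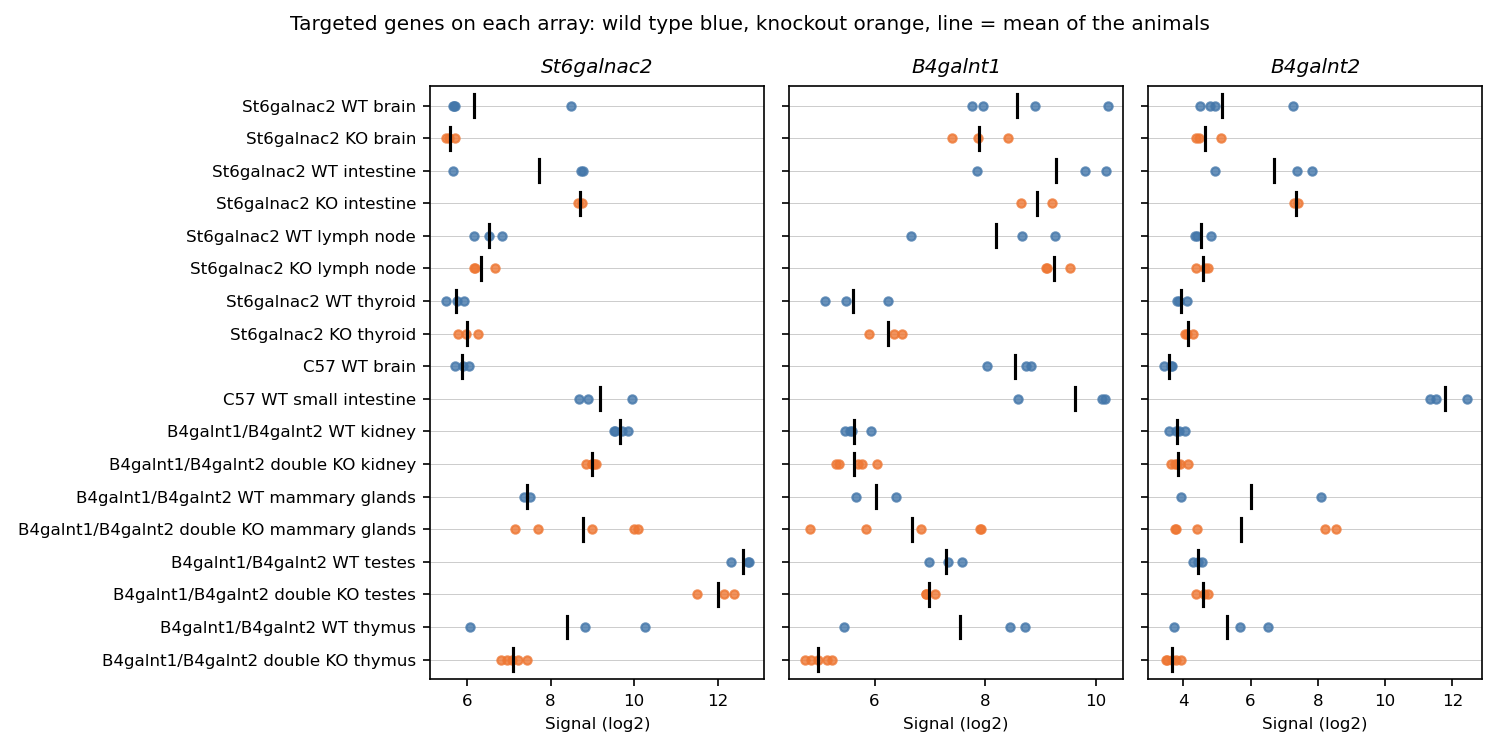
The log2 expression of St6galnac2, B4galnt1 and B4galnt2 on each of the 60 arrays, grouped by line, genotype and tissue, with a line at the mean of the animals. St6galnac2 was highest in testes, with means of 12.60 in WT and 12.01 in DKO, and B4galnt2 in C57 small intestine, with a mean of 11.77.

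Each array was next compared with the other arrays of its own and of every other tissue, by the correlation of its probe-set values after the mean of the tissue means was removed. For 56 arrays the best match was the labelled tissue, with a median correlation of 0.94 and a lowest of 0.513 for a WT lymph node array. The other 4 arrays stood apart. The first brain array of animal 9099 correlated at -0.274 with brain and 0.958 with intestine, and the intestine array of the same animal at -0.272 with intestine and 0.947 with brain. On that brain array the intestinal lectin genes Reg3b and Lgals4 read 13.46 and 13.61, whereas the 9 other brain arrays averaged 4.52 ± 0.16 (SD) for Reg3b, and Fut9 read 3.21 against 9.40 ± 0.40. On the intestine array Fut9 read 9.74 and Ugt8a 9.23, against means of 3.06 for both on the 7 other intestine arrays. The thymus arrays of WT animals N3740 and N3738 correlated at 0.043 and 0.058 with thymus and at 0.911 with each other. They read 13.41 and 13.51 for Prol1 and 9.31 and 9.57 for B3gnt6, where the 6 other thymus arrays averaged 2.55 and 4.34. They read 4.92 and 5.23 for Angpt1 and 7.09 and 6.50 for Igf2, where the others averaged 10.32 and 11.73. All 4 arrays keep their labels below, and counts without them are given beside the counts they affect.

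**Figure D2:**
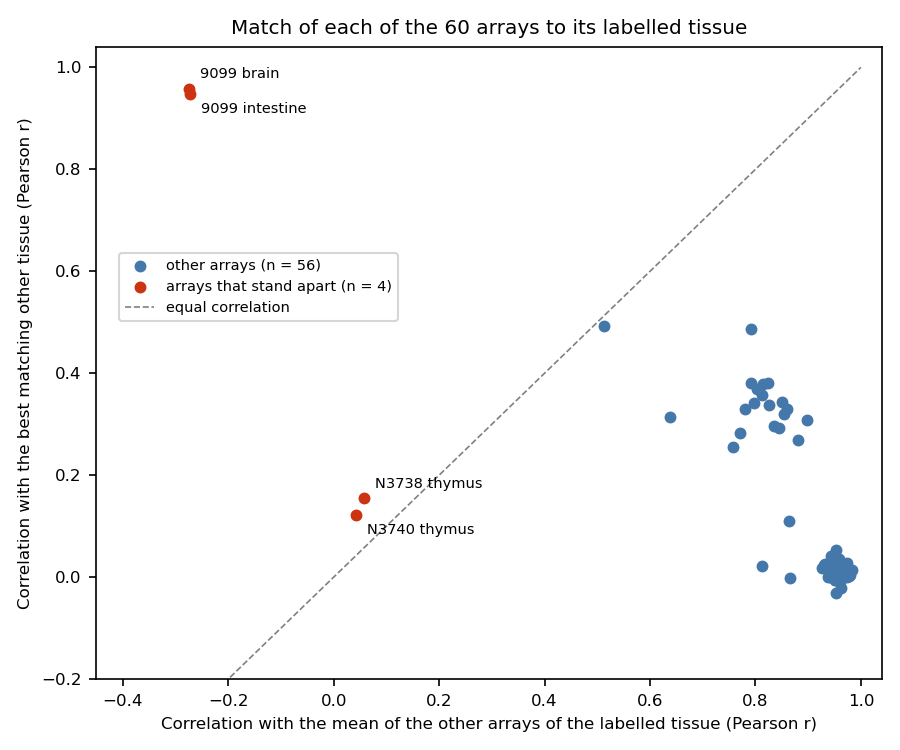
Correlation of each of the 60 arrays with its labelled tissue (horizontal axis) against its correlation with the best matching other tissue (vertical axis), each point an array. The 4 red arrays have correlations with their own tissue between -0.274 and 0.058, and the 56 blue arrays lie at 0.513 or above.

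In thyroid of St6galnac2 KO animals no gene was called with all of them in the fit and no block. The smallest p-values belonged to genes with lower values in KO, among them the growth factor receptor Fgfr2 at -1.34 ± 0.25, the asialoglycoprotein receptor Asgr1 at -1.03 ± 0.20, Chst11 at -0.82 ± 0.17 and the proteoglycan Fmod at -0.87 ± 0.19, which was lower in all 3 KO than in all 3 WT animals. Chga, a marker of hormone-storing granules, read 5.77 to 12.83 in KO and 12.73 to 13.06 in WT (-4.14 ± 1.02). By limma 0 of 963 probe sets were called and 42 had an unadjusted p under 0.05, the smallest adjusted p being 0.186. Igfbp2 (-0.75), Fzd1 (-0.62), Slc35c1 (-0.60), Glb1 (-0.54) and a probe set of Tenm4 (-0.87, the main Tenm4 probe set -0.58) followed, none passing. Without animal 9094, without animal 9093, or in males only, Fgfr2 at -1.75 (adjusted p = 0.031) and Chga at -6.12 (adjusted p = 0.00408) were called, and with animals of neighbouring numbers as a block Asgr1 was (-1.03, adjusted p = 0.0441). Of the gene lists, the 8 beta-GalNAc transferases were higher in KO as a set, with a median of 0.19, 0 higher and 0 lower called, 8 not called, and 0 adjusted over the list alone. B4galnt1, at 0.64 ± 0.21 (adjusted p = 0.95), had the smallest p of its members. The list's adjusted p was 0.00945, and the adjusted p = 0.84 with an estimated correlation. The list was not called without animal 9361 (adjusted p = 0.161), 9099 (adjusted p = 0.08), 9094 or 9093 (adjusted p = 0.153 for both).

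In lymph node the KO animals had higher values of the calcium channel gene Mcoln3 (1.38 ± 0.26) and the interleukin receptor gene Il27ra (0.95 ± 0.19), higher in all 3 KO than in all 3 WT animals. Lower values were seen for Adgre1 (-0.56), Csgalnact1 (-0.71), Igf2 (-0.79), Col14a1 (-0.80), Fst (-1.15), Fzd1 (-0.58), Fgfr1 (-0.67) and Ccl11 (-1.45). Fst, Ccl11 and Fgfr1 were at -0.68, -0.77 and -0.41 without WT animal 9094 or without KO animal 9093, which give the same fit because each is the only female of its genotype. The lymph node array of 9094 correlated at 0.513 with its own tissue and almost as well with mammary gland. None of these passed, since limma called 0 probe sets with 33 at an unadjusted p under 0.05 (smallest adjusted p = 0.801). Il27ra was called only when all groups of the line shared a fit (adjusted p = 0.0181). The 5 measured B-cell markers were higher in KO (median 0.79, 0 called in either direction, 5 not called, 0 adjusted over the list alone, Fcer2a 1.45 ± 0.62). The list's adjusted p was 0.00128, with an adjusted p = 0.936 with an estimated correlation, and its median dropped to 0.05 (adjusted p = 0.31) without animal 9094 or without animal 9093. The 45 interleukins and receptors had a median of 0.06 (adjusted p = 0.0459, adjusted p = 0.936 with an estimated correlation), with 0 higher, 0 lower, 45 not called and 0 adjusted over the list alone, and Il7 (0.84 ± 0.32) as the member with the smallest p. Its call ended without 9362 (adjusted p = 0.376), 9361 (adjusted p = 0.103), and 9094 or 9093, where the median was -0.09 (adjusted p = 0.866).

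In brain and intestine of the St6galnac2 line the smallest p-values belonged to modest differences. In brain Esm1 (-0.45 ± 0.13, its other probe set -0.05) and Naglu (-0.27 ± 0.10) were lower in all 3 KO animals, and B3galt6 was higher (0.32 ± 0.10). In intestine the sialyltransferase gene St3gal1 (1.07 ± 0.29), Igfbp6 (0.82 ± 0.27) and Bmp2 (1.87 ± 0.69) were higher in both KO animals than in all 3 WT animals, and Ccl20 differed by 3.09 ± 1.38. limma called 0 probe sets in brain (3 at an unadjusted p under 0.05, smallest adjusted p = 0.905) and 0 in intestine (2, smallest adjusted p = 0.991). Large2 (-0.26), Angptl2 (-0.49), Ube2g1 (-0.32), Il20 (0.22), Sult1c2 (-0.26), Cxcl12 (0.31) and Il31ra (0.21) completed the brain genes, and Egfr (0.87, its other probe set 0.32), Clec3b (0.49), Neu1 (0.61), Hbegf (0.43), Cxcl10 (0.93) and a probe set of Fut2 (0.41, the probe set that represents the gene -0.14) the intestine genes, none passing. Without the array of animal 9099 that stands apart, limma called 0 in brain (18 unadjusted) and, without its intestine array, 0 in intestine (60 unadjusted), where St6galnac2 differed by -0.05. The 8 markers of intestinal epithelium were lower in KO brain (median -0.98, adjusted p = 0.0148, adjusted p = 0.818 with an estimated correlation), and the 19 genes of chondroitin sulfate and linkage region were higher (median 0.28, adjusted p = 0.0107, adjusted p = 0.818 with an estimated correlation). Each list had 0 called members in either direction, all not called, and 0 adjusted over the list alone, and their smallest p-values belonged to Galnt4 (-0.84 ± 0.53) and B3galt6. Without the array of animal 9099 that stands apart both list calls ended, with medians of -0.03 (adjusted p = 0.734) and 0.08 (adjusted p = 0.696). Without animal 9361 they ended as well (adjusted p = 0.0644 and 0.232), and the epithelial list without animal 9100 (adjusted p = 0.246).

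Averaged over the 4 tissues of the line, the St6galnac2 KO effect on St6galnac2 itself was 0.09 ± 0.25 (adjusted p = 0.978). It was -0.01 without the arrays of 9099 that stand apart, -0.03 without animal 9099 and -0.02 without animal 9361. The smallest p-values were those of Galntl5 (-0.19 ± 0.05), Clec3a (-0.20 ± 0.05), Il27ra (0.22 ± 0.06) and Cxcl12 (0.37 ± 0.12, its other probe set 0.15), followed by Flt3l (0.26), Timd4 (0.46), Slc35e3 (-0.35), Cmah (0.36), Chga (-1.04) and Il18r1 (0.36), none passing (adjusted p = 0.976). limma called 0 probe sets for the mean (28 unadjusted) and 0 for a KO effect that differs between tissues (10 unadjusted), where Il27ra had the smallest p (adjusted p = 0.969). Bmp2, B3gnt9, Clec3a, Chga, Ccl20, Havcr1, Abo, Flt3l and Clec18a came after it (adjusted p = 0.988). The 5 B-cell markers were higher in KO over the 4 tissues (median 0.25, 0 called in either direction, 5 not called, 0 adjusted over the list alone, Fcer2a 0.40). That list's adjusted p was 0.00975, and 0.0552 without the arrays of 9099 that stand apart, 0.144 without 9362, and 0.513 without 9094 or 9093. For means over tissues no estimate of the correlation was made.

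DKO thymus had lower B4galnt1 (-2.47 ± 0.79) and B4galnt2 (-1.66 ± 0.63) than WT thymus, but without the 2 WT thymus arrays that stand apart the differences were -0.38 and -0.07 (adjusted p = 0.99). The receptor gene Fgfr2 (-1.41 ± 0.32), the natural killer receptor Klrd1 (-1.28 ± 0.31) and Cx3cl1 (-0.97 ± 0.24) were lower in all 5 DKO than in all 3 WT animals. Timd4 (1.03 ± 0.24), Lgals1 (1.16 ± 0.28), Mcam (1.20), Angptl4 (1.81), Ackr4 (0.85), Sult1a1 (1.52) and Gpc6 (2.15) had higher means. None passed: limma called 0 probe sets, 202 had an unadjusted p under 0.05, and all named genes had an adjusted p of 0.233. With all groups of the line in a single fit 267 were called (126 higher, 141 lower), B4galnt1 among them (adjusted p = 0.01). Without the 2 arrays that stand apart limma again called 0, with 27 unadjusted, and a single WT animal was left. Without that animal, N9700, 376 probe sets were called, B4galnt1 at -3.51 (adjusted p = 4.23e-06) and B4galnt2 at -2.45 (adjusted p = 0.000213) among them, the WT group then holding only the arrays that stand apart. The 8 connective tissue markers were higher in DKO (median 0.96, adjusted p = 0.00684, adjusted p = 0.841 with an estimated correlation), with 0 called in either direction, 8 not called, 0 adjusted over the list alone and Pdgfra (1.45 ± 0.49) as the member with the smallest p. Without the arrays that stand apart the list had a median of 0.19 and its test pointed the other way (adjusted p = 0.999).

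In DKO testes 3 genes fell. Ugt1a6b, which encodes a glucuronosyltransferase, fell by 1.14 ± 0.17 on the log2 scale. The Igf2 receptor gene Igf2r fell by 0.83 ± 0.12, and Hpse, which encodes an enzyme that cleaves heparan sulfate, fell by 0.85 ± 0.14. All 3 DKO animals lay below all 3 WT animals for each gene, and adjusted p was 0.0264, 0.0264 and 0.0402. The median over all probe sets was -0.11, and after each array was centred on its median Hpse was at -0.80 (adjusted p = 0.0538). B4galnt1 differed by -0.32 ± 0.16 (adjusted p = 0.439) and B4galnt2 by 0.15 ± 0.14 (adjusted p = 0.619). The calls depended on single animals. With each animal left out in turn, Ugt1a6b ran from -1.28 to -0.98, Igf2r from -0.91 to -0.76 and Hpse from -0.99 to -0.77. limma called 0 probe sets without N3740, N3738, N5895, N5894 or N5893, and 205 without N9700, among them B4galnt1 at -0.47 (adjusted p = 0.0248). Without N3740 and N3738 together N9700 was the only WT animal left. Ugt1a6b was then at -0.85, Igf2r at -0.66 and Hpse at -0.58, and with a single WT animal the calls cannot be judged. Asah1 (-0.65), Tgfbr2 (-0.63, its other probe set 0.17), Met (-0.50), Ube2g1 (-0.71), Igf2 (-0.50) and Gpc2 (0.53) did not pass, except without N9700. The 24 genes of lysosomal glycan degradation were lower in DKO (median -0.25, 0 called in either direction, 24 not called, 1 adjusted over the list alone, Asah1 with the smallest p). That list had an adjusted p of 0.0228 and an adjusted p = 0.991 with an estimated correlation, and it was not called without N3740 (adjusted p = 0.0774), N3738 (adjusted p = 0.175), N5893 (adjusted p = 0.263) or N3740 and N3738 together (median -0.06, adjusted p = 0.641). The 45 interleukins and receptors tested as higher (adjusted p = 0.0191, adjusted p = 0.991 with an estimated correlation) although their median was -0.003, with 0 called in either direction, 45 not called, 0 adjusted over the list alone and Il6st (-0.58 ± 0.16) as the member with the smallest p. They were not called without N3738 (adjusted p = 0.569) or N5894 (adjusted p = 0.0529), and both lists ended after a second quantile normalization (adjusted p = 0.303 and 0.395).

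In DKO mammary gland the genes with the smallest p-values included Ccl7 at -2.73 ± 0.39, Cxcl13 at -2.29 ± 0.34 and Ccl8 at -1.61 ± 0.28, for which each of the 5 DKO animals lay below both WT animals. The vesicle trafficking gene Rab7 (1.40 ± 0.18) and the nucleotide sugar transporter gene Slc35a3 (1.01 ± 0.17) had higher values in all 5 DKO animals. None passed, with 0 called by limma, 97 at an unadjusted p under 0.05 and a smallest adjusted p of 0.143. With all groups of the line in a single fit 34 were called (2 higher, 32 lower). Hs3st5 (-1.20), Klrd1 (-1.08), Cxcr3 (-0.71), Klra9 (-0.94) and Snrnp27 (-0.71) completed the named genes. B4galnt1 differed by 0.75 ± 0.80 (adjusted p = 0.818) and B4galnt2 by -0.09 ± 1.71 (adjusted p = 0.991), the latter running from -1.79 without N3738 to 1.42 without N9686, above 0 when any 1 of 4 animals was left out. limma called 2 probe sets without N5895, Rab7 at 1.48 (adjusted p = 0.0303) and Cxcl13 at -2.09 (adjusted p = 0.00754). After a second quantile normalization it called Rab7 alone (1.48, adjusted p = 0.012). As sets, the 46 chemokines and receptors were lower (median -0.29, adjusted p = 0.00146, adjusted p = 0.957 with an estimated correlation), with 0 called in either direction, 46 not called, 9 adjusted over the list alone and Ccl7 as the member with the smallest p. The 10 markers of macrophages and myeloid cells were lower too (median -0.62, adjusted p = 0.01, adjusted p = 0.957 with an estimated correlation), with 0 called in either direction, 10 not called, 0 adjusted over the list alone and Siglec1 (-0.42 ± 0.12) first. With 1 WT animal, the chemokine and macrophage medians were -0.20 and -0.83 without N9686, and the latter was -0.30 without N3738.

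St6galnac2 fell in DKO kidney, by 0.65 ± 0.08 on the log2 scale, from 9.65 ± 0.15 (SD, n = 4) to 8.99 ± 0.09 (n = 5). All 5 DKO arrays lay below all 4 WT arrays, and the adjusted p of 0.00661 was the only limma call, with 129 probe sets at an unadjusted p under 0.05. The call ended without N9686 (-0.66, adjusted p = 0.0578), in males only (-0.66, adjusted p = 0.12), when all groups of the line shared a fit (adjusted p = 0.987) and without N3740 and N3738 (-0.55 ± 0.08, adjusted p = 0.106), while the difference stayed between -0.70 and -0.60 when animals were left out singly. B4galnt1 (-0.07 ± 0.10) and B4galnt2 (0.03 ± 0.12) were close to their WT levels. At the WT mean of B4galnt2 (3.83) a loss could hardly show. Ppbp (-0.87 ± 0.16, adjusted p = 0.112) did not pass, but did without N9700 (-1.0, adjusted p = 0.0118) or N5894 (-0.97, adjusted p = 0.05). Eif5 (-0.37), Fgf1 (-0.51), Galnt18 (-0.37), Lgalsl (-0.33), Cd93 (0.39), Esm1 (-0.78, its other probe set -0.13), Chodl (-0.28) and Papss1 (-0.35) did not pass either. The 10 endothelial markers were higher in DKO (median 0.18, adjusted p = 0.000738, adjusted p = 0.818 with an estimated correlation), with 0 called in either direction, 10 not called, 2 adjusted over the list alone and Cd93 (0.39 ± 0.10) first. The 8 connective tissue markers were higher as well (median 0.17, adjusted p = 0.000738, adjusted p = 0.75 with an estimated correlation), with 0 called in either direction, 8 not called, 0 adjusted over the list alone and Dcn (0.31 ± 0.13) first. Without N3740 and N3738 the medians were 0.06 and 0.09 (adjusted p = 0.277 for both). With single animals left out the endothelial median ran from 0.086 (N5893) to 0.26 (N9686). The connective tissue median ran from 0.091 (N9686) to 0.22 (N9700).

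Averaged over thymus, testes, mammary gland and kidney, DKO animals expressed less of 6 genes and more of 2. Klrd1 fell by 0.67 ± 0.11 on the log2 scale (adjusted p = 0.00449) and the chemokine receptor gene Cxcr3 fell by 0.35 ± 0.06 (adjusted p = 0.00533). The chemokine gene Ccl5 at -0.72 ± 0.16, Mcoln2 at -0.45 ± 0.10 (adjusted p = 0.038 for both), Il12a at -0.27 ± 0.06 and Hes5 at -0.23 ± 0.06 (adjusted p = 0.0495 for both) were also lower. Rab7 rose by 0.96 ± 0.21 (adjusted p = 0.038). The estimate for Klrd1 was below 0 in all 4 tissues, at -1.28, -0.19, -1.08 and -0.12 in that order, and that for Cxcr3 at -0.48, -0.10, -0.71 and -0.10. The 8 calls, 2 higher and 6 lower, came with 248 unadjusted, and Ccl7 (-0.70, adjusted p = 0.0554) and Fut4 (-0.45, its other probe sets -0.19 and -0.30, adjusted p = 0.056) did not pass. B4galnt1 averaged -0.51 ± 0.33 (adjusted p = 0.326) and B4galnt2 -0.42 ± 0.51 (adjusted p = 0.595), but without N3740 and N3738 B4galnt1 was at 0.15, and without N9686 B4galnt2 was at 0.0028. Without the 2 WT thymus arrays that stand apart 5 genes were called, 0 higher and 5 lower, of which 3 were shared, namely Klrd1, Cxcr3 and Ccl5. A second quantile normalization left 3 higher and 2 lower, and centring each array 2 and 2, while without the animal block 49 were called (4 higher, 45 lower). Single animals moved the count to 317 (N9700), 3 (N3740), 1 (N3738), 3 (N5895), 2 (N5894), 2 (N5893), 2 (N5892) and 2 (N5891). Ccl5, Il12a and Hes5 lost their calls whenever a single animal other than N9700 was left out, Mcoln2 whenever it was other than N9700 or N9686, and Rab7 whenever it was other than N9700 or N3740. B4galnt1 was called without N9700 (-0.83, adjusted p = 0.0167), Fut4 without N9700 and Ccl7 without N9700 or N5895 (adjusted p = 0.0218). Klrd1 kept its call without each animal in turn but had an adjusted p of 0.0578 without N3740 and N3738, and Cxcr3 lost its call without N3738 (adjusted p = 0.0755) and N5893 (adjusted p = 0.0575). The 46 chemokines and receptors were lower as a set (median -0.15, adjusted p = 0.0124, 0 higher, 2 lower, 44 not called, 16 adjusted over the list alone, Cxcr3 and Ccl5), and were not called without the arrays that stand apart (adjusted p = 0.0692), N9700 (adjusted p = 0.12), N5892 (adjusted p = 0.0661) or N9686 (adjusted p = 0.148), or after a second quantile normalization (adjusted p = 0.052). The 8 connective tissue markers were higher (median 0.21, adjusted p = 0.00386, 0 called in either direction, 8 not called, 0 adjusted over the list alone, Lum 0.39 ± 0.21), and had a median of -0.03 without those arrays.

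The DKO effect differed between tissues for 33 probe sets, the largest single-tissue effect being in thymus for 18, mammary gland for 13, testes for 2 and kidney for 0. Igf2r was 0.28, -0.83, 0.29 and -0.28 in thymus, testes, mammary gland and kidney (adjusted p = 0.0028). The estimate for Ccl7 was clearly below 0 only in mammary gland, at -2.73 against -0.09 to 0.05 elsewhere (adjusted p = 0.0028 for the difference between tissues). That for Hs3st5 was likewise lowest there, at -1.20 (adjusted p = 0.0183 for the difference). Neither gene was called within mammary gland. Lgalsl was 0.65, -0.18, -0.85 and -0.33 in the same order (adjusted p = 0.00521) and Ccl9 0.83, 0.10, -1.19 and -0.13 (adjusted p = 0.024). Ugt1a6b (adjusted p = 0.0249), Klrd1 (adjusted p = 0.035), Il12a (adjusted p = 0.0404), Ccl5 (adjusted p = 0.0479) and Cxcr3 (adjusted p = 0.049) were also among them, as were Clec4a3, Man2a1, Gpc6, Pgm1, Fcer2a, Tgfbr3, Csf1r, Clec4b1, Sdc2, Gpc1, Igf2, St3gal3, Cd48, Klra2, Fgf1, Ccl22, Ccr1, B4gat1, Slc35a4 and B3galnt2. A probe set of Il1rl1 was also called (adjusted p = 0.035), while the probe set that represents that gene did not (adjusted p = 0.6945). B4galnt1 did not pass (adjusted p = 0.0785). After centring each array 10 were called, after a second quantile normalization 17 and without the animal block 13. Without the 2 WT thymus arrays that stand apart 6 were called, 5 of them shared. Leaving out an animal gave 363 (N9700), 2 (N3740), 0 (N3738, by limma), 8 (N5895), 13 (N5894), 12 (N5893), 3 (N5892), 19 (N5891) and 13 (N9686).

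Compared with C57 small intestine, St6galnac2 KO intestine expressed far less B4galnt2, which fell by 4.42 ± 0.35 on the log2 scale from a mean of 11.77 ± 0.58 (SD, n = 3) to 7.35 ± 0.08 (n = 2). Both KO animals lay below all 3 C57 animals, the adjusted p was 0.0214, and 137 probe sets had an unadjusted p under 0.05. WT intestine of the same line showed -5.06 ± 0.83 against C57, which limma did not call (0 called, 112 unadjusted, adjusted p = 0.317). Without the intestine array of animal 9099 that stands apart it was called, at -4.17 ± 0.37 (adjusted p = 0.0475), so the lower level was not confined to the KO. The strain background of the line is not stated, and its samples are labelled intestine where those of C57 are labelled small intestine, so background and part of the gut could each account for the difference. The call in KO ended without GDWTF1 (-4.54, adjusted p = 0.192) and after a second quantile normalization (-4.22, adjusted p = 0.0671). B4galnt2 was at -4.47 without 9361 and -4.37 without 9093, with 1 KO animal left. Without GDWTF2 2 probe sets were called. The medians over all probe sets were -0.26 for KO and -0.25 for WT against C57, to be set against every difference in these comparisons. St6galnac2 was -0.47 ± 0.40 in KO (adjusted p = 0.544) and -1.44 ± 0.95 in WT (adjusted p = 0.559). In KO, Fgfr3 (-1.81), Fgf13 (-1.98), Galnt7 (1.43), Il10ra (-0.92), Ly75 (1.63), Erbb3 (2.06), Csf2rb (-1.35), Fcrla (-1.47) and a probe set of Fut4 (-2.38, its other probe sets -0.89 and -1.11) did not pass (adjusted p = 0.253). In WT, Fgf15 (-3.32), Cxcl12 (-1.33, its other probe set -0.73), Tgfbr2 (-1.75, its other probe set -0.07), Fcrla (-1.72), Cd93 (-1.12), Angptl2 (-1.31), Il1r1 (-0.71), Csf2rb2 (-1.30) and B4galt5 (-0.97) did not pass. In WT the 9 neural markers were higher (median 1.41, adjusted p = 0.000444, adjusted p = 0.716 with an estimated correlation, Galnt13 1.44 ± 1.17) and the 10 endothelial markers lower (median -0.59, adjusted p = 0.00351, adjusted p = 0.633 with an estimated correlation, Cd93). The first list had 0 called in either direction, 9 not called and 0 adjusted over the list alone, and the second 0, 10 and 2. The 5 B-cell markers (median -0.94, adjusted p = 0.0354, adjusted p = 0.633 with an estimated correlation, Fcer2a) and 49 C-type lectins (median -0.43, adjusted p = 0.04, adjusted p = 0.842 with an estimated correlation, Cd93) were lower, with 0 called members and 1 and 0 adjusted over the list alone. Without the array of 9099 none of these lists was called, and the neural median was -0.24. The C-type lectins were not called without GDWTM3 (adjusted p = 0.0613), GDWTF2 (adjusted p = 0.0511) or GDWTF1 (adjusted p = 0.0677) or after centring (adjusted p = 0.112), the B-cell markers without GDWTF2 (adjusted p = 0.0588), and the neural markers after centring (adjusted p = 0.0665).

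Against C57 brain no gene was called. B4galnt2 read 4.39 to 5.13 in KO brain, against 3.41 to 3.67 in C57 (1.09 ± 0.21, adjusted p = 0.093), and 4.51 to 6.11 in WT brain (1.57 ± 0.43, adjusted p = 0.349). Hp1bp3 was lower in all 3 KO animals (-0.62 ± 0.07) and all 3 WT animals (-0.74 ± 0.15), and Rab7 was higher in WT (1.18 ± 0.19). limma called 0 probe sets in KO (197 unadjusted, smallest adjusted p = 0.0903) and 0 in WT (103 unadjusted, smallest adjusted p = 0.344), with medians over all probe sets of -0.15 and -0.14. With all probe sets of the array tested 11 were called in KO, Hp1bp3, Fut4 and Bgn among them. Without the brain array of animal 9099 that stands apart B4galnt2 in WT was 1.18 ± 0.14 (adjusted p = 0.0641), with 0 called by limma and 246 unadjusted. St6galnac2 was -0.30 ± 0.12 in KO (adjusted p = 0.233) and 0.27 ± 0.41 in WT (adjusted p = 0.763), the latter turning to -0.20 without that array or without animal 9099. The other KO genes were Fut4 (-0.67, its other probe sets -0.19 and -0.27), Bgn (-0.68), Huwe1 (-0.71), Klra9 (-0.98), Ube2g1 (-0.71), Il10ra (-0.49), Clec2d (-0.77), Copg1 (-0.51) and Acvr1 (-0.65), and the other WT genes Cxcr2 (0.66, its other probe set 0.01), Hs2st1 (-0.62), B3galt6 (-0.87), Rrn3 (-0.80), Slc35a5 (-0.59), Bmp4 (-0.51), Notch3 (-0.81) and Ube2r2 (-0.49), none passing. In WT brain the 8 markers of intestinal epithelium tested higher (median 0.88, adjusted p = 0.0391, adjusted p = 0.937 with an estimated correlation, 0 called in either direction, 8 not called, 0 adjusted over the list alone, B3gnt6 -0.21 ± 0.17), and their median was -0.17 without that array. The list was not called without GDWTM3 (adjusted p = 0.0524) or GDWTF2 (adjusted p = 0.207), or after centring (adjusted p = 0.165).

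Among WT tissues of the St6galnac2 line, thyroid was marked by Chga (4.62 ± 0.32 above the mean of the other 3 tissues), Angptl1 (4.27), the chemokines Ccl11 (3.75) and Pf4 (3.58) and the collagen gene Col14a1 (3.49). B4galnt1 was lower than elsewhere (-3.08 ± 0.63, adjusted p = 0.013), as was the lactosylceramide synthase gene B4galt6 (-2.85 ± 0.17). In all, 83 probe sets were called, 54 higher and 29 lower, at an adjusted p under 0.05 and a log2 difference of at least 1, and 164 (66 and 98, 81 shared) without the arrays that stand apart. Without animal 9362 the count was 2, and B4galnt1, Angptl1, Ccl11, Pf4 and Col14a1 were no longer called, and Ccl11 was not called without 9094 either (adjusted p = 0.0753). The 18 genes of ganglioside and glycolipid synthesis were lower (median -1.04, adjusted p = 0.0247, adjusted p = 0.403 with an estimated correlation), with 0 higher, 5 lower, 13 not called, 6 adjusted over the list alone, B4galt6, Gal3st1 (-1.66), Ugcg (-2.30) and B4galnt1 first. Without the arrays that stand apart that list was not called (adjusted p = 0.134), nor without 9099 (adjusted p = 0.18), after centring (adjusted p = 0.0611) or without dim probe sets (adjusted p = 0.0565). The 8 connective tissue markers were higher (median 1.68, adjusted p = 0.00213, adjusted p = 0.231 with an estimated correlation), with 6 higher, 0 lower, 2 not called, 6 adjusted over the list alone and Mrc2 (1.48), Dcn (2.51), Pdgfra (1.89) and Lum (3.28) first.

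Lymph node was marked by the endothelial selectin ligand Glycam1 at 7.82 ± 0.28, Cxcl13 at 5.54, Fcrla at 5.11 and Cd2 at 4.63 above the other tissues, and Chga at -5.35 ± 0.32. Every lymph node sample exceeded all other WT samples of the line for the first 4 genes. The called probe sets numbered 142, 110 higher and 32 lower (94 and 60 after centring), with 212 (118 and 94, 139 shared) without the arrays that stand apart. The count was 28 without animal 9362, where Cxcl13 was not called (adjusted p = 0.0825). Ccl25 (-2.93, adjusted p = 0.137) was not called with all arrays. The 46 chemokines and receptors were higher (median 0.64, adjusted p = 1.35e-06, adjusted p = 0.321 with an estimated correlation), with 20 higher, 2 lower, 24 not called, 23 adjusted over the list alone and Ccr6 (3.17), Ccr2 (2.17), Ccl8 (3.81) and Ccl7 (2.63) first. All 5 B-cell markers were higher (median 3.99, 5 higher, 0 lower, 0 not called, 5 adjusted over the list alone, adjusted p = 0.000199, adjusted p = 0.285 with an estimated correlation), Cd22 (3.99), Fcer2a (4.16), Siglecg (2.96) and Cd72 (4.38) first. Of the 49 C-type lectins (median 0.42, adjusted p = 0.000268, adjusted p = 0.343 with an estimated correlation) 12 were higher, 1 lower and 36 not called, 13 adjusted over the list alone, Cd209d (2.85), Clec10a (2.44), Cd209b (4.58) and Fcer2a first. Siglecs, with 4 higher, 0 lower and 5 not called of 9 and 4 adjusted over the list alone (median 0.28, adjusted p = 0.0296, adjusted p = 0.268 with an estimated correlation, Cd22, Siglecg, Siglec1 1.59 and Siglech 2.25), were not called without the arrays that stand apart (adjusted p = 0.129), without 9099 (adjusted p = 0.21) or after a second quantile normalization (adjusted p = 0.063).

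Brain was marked by the fucosyltransferase Fut9 (4.50 ± 1.33, adjusted p = 0.049), the galactolipid synthase gene Ugt8a (4.30), Spock1 (4.27), Ptprz1 (3.73) and Fgf12 (3.68), and by low Ccl11 (-3.95) and Cxcl13 (-3.33). Without the arrays of animal 9099 that stand apart the same 7 differences were 6.37, 5.95, 5.99, 5.26, 5.10, -4.96 and -4.16. The median over all probe sets was -0.15. Calls numbered 97, 47 higher and 50 lower (67 and 40 after centring), and 332, 170 and 162, without those arrays. With the animal as a block 53 were called, and Fut9 (adjusted p = 0.0658), Ugt8a, Spock1, Ptprz1, Fgf12 and Cxcl13 were not. All 7 named genes lost their calls without animal 9362 or without animal 9094, and the count was 3 without 9362, 29 without 9094 and 282 without 9099. The 9 neural markers were higher (median 3.38, adjusted p = 4.38e-05, adjusted p = 0.435 with an estimated correlation), with 6 higher, 0 lower, 3 not called, 9 adjusted over the list alone and L1cam (3.08), St8sia3 (3.38), Ncan (3.16) and Ugt8a first. Ganglioside and glycolipid genes were higher (18 measured, median 1.17, adjusted p = 0.000714, adjusted p = 0.361 with an estimated correlation), with 4 higher, 0 lower, 14 not called and 4 adjusted over the list alone, B4galt6 (2.65), Gal3st1 (1.44), St8sia3 and Ugt8a. C-type lectins were lower (49 measured, median -0.53, adjusted p = 1.61e-05, adjusted p = 0.361 with an estimated correlation), with 0 higher, 9 lower, 40 not called, 11 adjusted over the list alone and Clec10a (-2.07), Cd209d (-1.99), Mrc1 (-2.30) and Cd209b (-2.28) first.

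In intestine Reg1 was 5.06 ± 1.55 above the other tissues, which was not called (adjusted p = 0.077), and 8.15 without the arrays that stand apart (adjusted p = 9.8e-10), and Reg3b (4.99 and 8.31), Dmbt1 (4.48 and 7.53), Lgals2 (4.33 and 7.07) and Ccl25 (4.14 and 6.64) moved likewise. B4galnt2 was higher than elsewhere, at 2.18 ± 0.55 (adjusted p = 0.048), and at 3.19 (adjusted p = 1.1e-06) without those arrays, but was not called without 9362 or without 9094. Glycam1 (-2.98 ± 0.28) and Notch2 (-2.61 ± 0.43) were lower, Notch2 not being called without 9362. The median over all probe sets was -0.20, and 48 probe sets were called, 14 higher and 34 lower (19 and 21 after centring), against 275 (122 and 153, 45 shared) without those arrays. With the animal as a block 22 were called and B4galnt2 was not (adjusted p = 0.064). The count was 3 without 9362, 27 without 9094 and 258 without 9099. The 17 nucleotide sugar transporters were higher (median 0.60, adjusted p = 0.000957, adjusted p = 0.0999 with an estimated correlation), with 2 higher, 0 lower, 15 not called, 3 adjusted over the list alone, Slc35c2 (1.70) and Slc35d1 (1.28). The 8 markers of intestinal epithelium were higher (median 3.76, adjusted p = 0.000957, adjusted p = 0.579 with an estimated correlation), with 0 called in either direction, 8 not called, 6 adjusted over the list alone and Reg1 first, and 7 were called higher without those arrays.

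**Figure D3:**
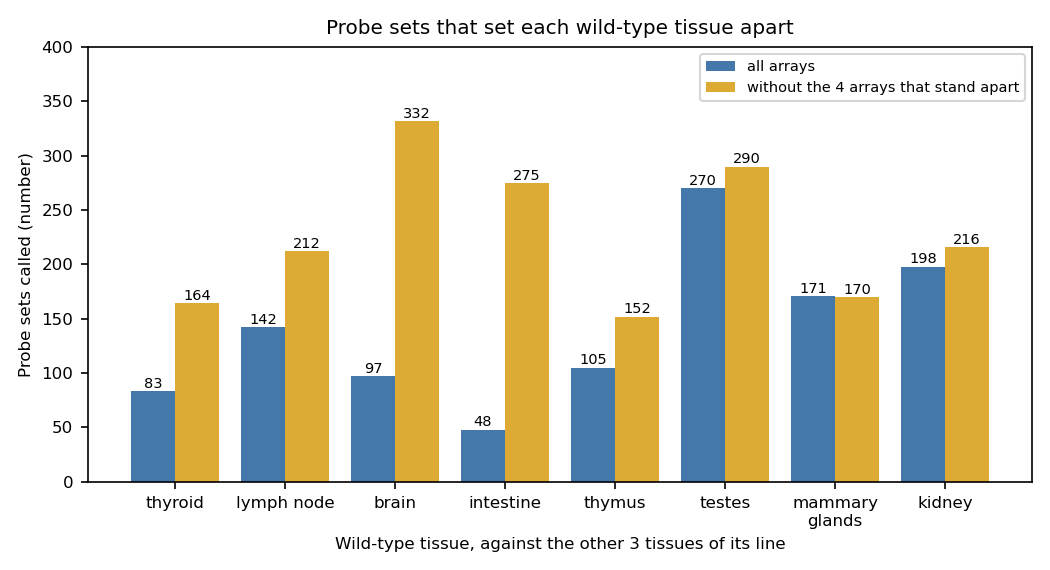
Number of probe sets called in each WT tissue against the other 3 tissues of its line, with all arrays and without the 4 arrays that stand apart. The bars for brain go from 97 to 332, those for intestine from 48 to 275, and those for testes from 270 to 290.

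In WT mice of the B4galnt1/B4galnt2 line, testes had the most distinct profile. The spermatid transferase gene Galntl5 (7.53 ± 0.32), Rpl39l (5.52), the integrin gene Itgae (5.31), Igf2bp3 (5.26, its other probe set 3.27) and the Notch ligand Dll3 (5.14) were higher on every testes array than on any other WT array of the line, and Igfbp5 (-5.16) and Vegfa (-4.81) were lower. St6galnac2 was 4.10 ± 0.64 higher (adjusted p = 0.000302), the 3 testes animals reading 12.31 to 12.74. Of 963 probe sets 270 were called, 90 higher and 180 lower, and 290 (257 shared) without the arrays that stand apart. No list was called by its set test. Of the 19 sialyltransferases 3 were higher, 6 lower and 10 not called, 9 adjusted over the list alone (median -0.27, adjusted p = 0.944), with St8sia4 (-2.94), St8sia2 (2.57), St8sia1 (-1.59) and St3gal5 (1.24) first. Of the 10 galectins (median -0.56, adjusted p = 0.779) 0 were higher, 5 lower and 5 not called, 5 adjusted over the list alone, with Lgals3 (-2.63), Lgalsl (-1.32), Lgals12 (-1.42) and Lgals1 (-1.43) first.

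Kidney was marked by Fut9 (6.78 ± 0.21), the uromodulin gene Umod (6.75 ± 0.38), the sulfotransferase Sult1d1 (6.04), Igfbp1 (4.73) and the ganglioside sialyltransferase St8sia1 (4.51), each higher on all 4 kidney arrays than on any other WT array of the line. Rpl39l was lower (-4.05), and so was Prol1 (-4.68 ± 1.70, adjusted p = 0.0445), which was not called after centring (adjusted p = 0.0551) or without N3740 (adjusted p = 0.155), N3738 (adjusted p = 0.223) or N9686 (adjusted p = 0.147). The median over all probe sets was -0.16, and 198 were called, 116 higher and 82 lower, with 216 (182 shared) without the arrays that stand apart. The 24 lysosomal genes of glycan degradation were higher (median 0.52, adjusted p = 0.00555, adjusted p = 0.84 with an estimated correlation), with 7 higher, 1 lower, 16 not called, 8 adjusted over the list alone and Neu1 (3.97), Arsb (2.58), Manba (1.95) and Glb1 (2.19) first. The 46 chemokines and receptors were lower (median -0.42, adjusted p = 0.00555, adjusted p = 0.84 with an estimated correlation), with 2 higher, 8 lower, 36 not called, 10 adjusted over the list alone and Ccl7 (-2.04), Ccl11 (-2.48), Ccl9 (-1.23) and Ccl8 (-3.07) first.

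Mammary gland was marked by Clec10a at 4.84 ± 0.24, Ccl8 at 4.54, Mgl2 at 4.45 and Lum at 4.41 above the other tissues, and Hk1 (-2.96) and Cks2 (-2.93) below. Prol1 (4.55, adjusted p = 0.147) was not called with all arrays and stood at 6.98 without the 2 thymus arrays that stand apart, and at 3.24 (adjusted p = 1.38e-05) without N9700. St6galnac2 was lower (-2.77 ± 0.73, adjusted p = 0.0156) but not called without N3738 (adjusted p = 0.256) or N9686 (adjusted p = 0.134). Calls numbered 171, 130 higher and 41 lower (108 and 62 after a second quantile normalization), 170 (150 shared) without those arrays, and 107 without N3738. The 10 markers of macrophages and myeloid cells were higher (median 1.96, adjusted p = 0.000123, adjusted p = 0.205 with an estimated correlation), with 6 higher, 0 lower, 4 not called, 6 adjusted over the list alone and Clec10a, Mgl2, Adgre1 (2.84) and Csf1r (2.22) first. Of the 3 WT thymus arrays 2 stand apart. B3gnt6 (3.35 ± 0.84, adjusted p = 0.0169) was at 0.07 without them (adjusted p = 0.866), and Prol1 (4.64 ± 1.86, adjusted p = 0.112) at -2.66 (adjusted p = 0.00042). B3gnt6 was not called without N3740 or without N3738, and Prol1 was called without N9700 (8.20, adjusted p = 1.03e-07). Cxcl13 (3.14, and 4.78 without them) and the hyaluronan receptor Cd44 (3.09 ± 0.28, and 2.57) were higher and Ugt1a6b (-3.90, and -2.46) and Rpl39l (-2.97, and -2.87) lower either way. In thymus 105 were called, 43 higher and 62 lower, 152 (60 shared) without those arrays and 52 without N3738.

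Sex had a large effect on kidney. Comparing 3 females with 6 males across genotypes, females had higher Igf2 (2.90 ± 0.19, adjusted p = 5.55e-06), Lum (1.35 ± 0.18), Ugt1a6b (1.08 ± 0.12), Igfbp1 (1.07 ± 0.28), Fst (1.05), B3galnt1 (1.01), Tenm4 (0.95, its other probe set 1.17) and Mcoln2 (0.89). They had lower Ugt8a (-2.95 ± 0.16, adjusted p = 2.02e-06), the chondroitin sulfotransferase genes Chst7 (-2.72 ± 0.27) and Chst11 (-2.04 ± 0.27), Ugt2b5 (-1.84, its other probe set -0.72), the keratan sulfate sulfatase Galns (-1.69 ± 0.13), Timd2 (-1.30), Angptl4 (-1.30), Angptl7 (-1.12), Csgalnact1 (-1.07) and Sdc2 (-0.85). All 3 females lay beyond all 6 males for every gene named but Angptl7. B4galnt1 was higher in females (0.44 ± 0.10, adjusted p = 0.0235). Calls numbered 87, 62 higher and 25 lower (58 and 41 after a second quantile normalization), and 44 without N5892, 49 without N9686, 55 without N5891 and 111 without N5893. Single animals ended the call of B4galnt1 (N5895, N9686, N5894 or N5892), Igfbp1 (N5895, N9686, N3740, N5894, N5892 or N5891), Angptl7 (N5895, N9686 or N5892), and B3galnt1 and Csgalnact1 (N9686, adjusted p = 0.0812 and 0.118). Of the 19 genes of chondroitin sulfate and linkage region (median -0.04, adjusted p = 0.743) 1 was higher, 3 lower and 15 not called, 8 adjusted over the list alone, with Chst7, Chst11, Csgalnact1 and Csgalnact2 (0.37) first. The 8 connective tissue markers were higher in females (median 0.35, adjusted p = 0.00963, adjusted p = 0.97 with an estimated correlation), with 4 higher, 0 lower, 4 not called, 5 adjusted over the list alone and Lum, Bgn (0.42), Pdgfra (0.50) and Dcn (0.54) first.

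**Figure D4:**
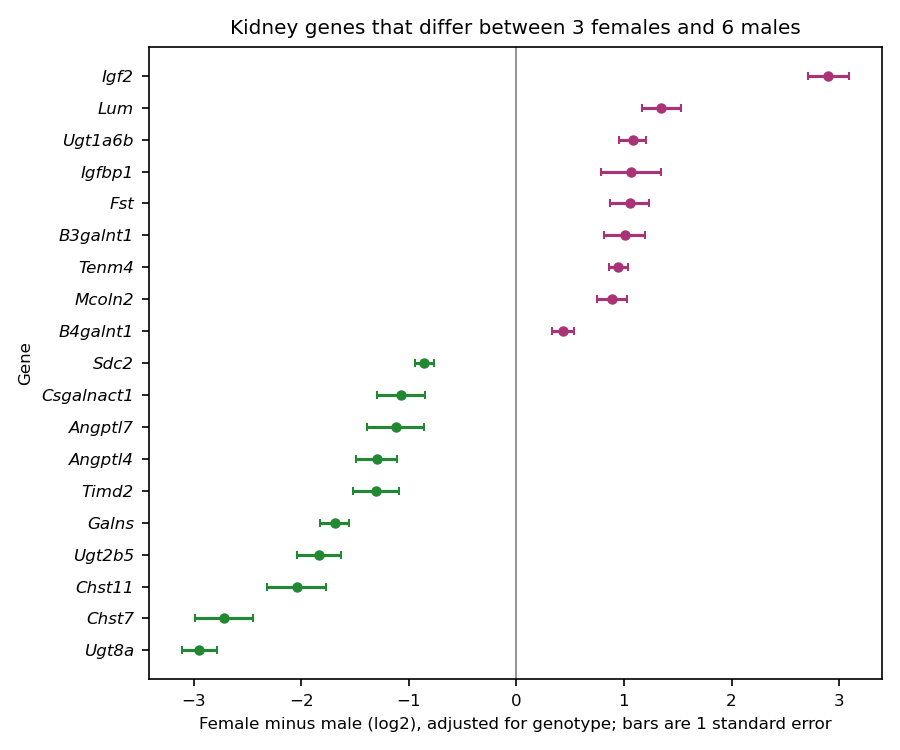
Female minus male log2 difference with 1 SE for 19 called kidney genes named in the text, from 3 females and 6 males. Igf2 stands highest at 2.90, and Ugt8a and Chst7 lowest at -2.95 and -2.72.

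In mammary gland 3 genes were higher in the 3 females than in the 4 males, the epidermal growth factor family gene Areg (5.64 ± 0.54), the mucosal glycoprotein gene Dmbt1 (4.13 ± 0.43) and the transporter gene Slc35f3 (2.17 ± 0.20), each in every female against every male (adjusted p = 0.017). Muc1 (1.33, adjusted p = 0.0518), Fzd6 (1.43, adjusted p = 0.0714), Mdk (1.48), Cd164 (0.91), Cx3cl1 (1.42), Fzd7 (1.02) and Papss1 (0.56) did not pass, and 111 probe sets had an unadjusted p under 0.05. limma called 0 without N3738, N9686, N5894, N5892 or N5891, 14 without N5895 and 5 without N5893. Of the targeted genes, B4galnt1 was 1.05 ± 0.73 (adjusted p = 0.686), B4galnt2 1.90 ± 1.57 (adjusted p = 0.745) and St6galnac2 0.79 ± 0.76 (adjusted p = 0.771).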

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

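The tests on the arrays of animal 9099, on the thymus arrays of N3740 and N3738, on the kidney difference without these animals and on splits of the testes were chosen only after the result was seen, and the tests on flanking DNA and on the other splits before.

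The first brain array and the intestine array of animal 9099 each resembled the tissue of the other label. The lower of the correlations of each array with the other's labelled tissue was 0.947, which may mean that the labels of both arrays were exchanged. A mixture of brain and intestine RNA was argued against, since genes high in brain alone read, in the median, -0.103 on that brain array relative to the intestine arrays, that is, at about the intestine level. The second brain array of the same animal correlated at 0.99 with the intestine array and at -0.325 with the first brain array. No biological explanation was tested, and an exchange at any step from dissection to labelling stays open.

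The WT thymus arrays of N3740 and N3738 resembled each other and not the other thymus arrays. A label of another tissue of this series was argued against, the highest correlation of either array with another tissue being 0.155. A mixture with a sizeable share of thymus RNA was argued against by genes high in thymus alone, which dropped by 4.68 or more in the median on both arrays. Only 4 measured genes were of that kind, so this rests on few genes. RNA of a tissue outside the series could give such arrays and was not tested, since no profile of it was available. The genotype of these animals is WT by label, and the DKO thymus arrays resembled the thymus array of WT animal N9700, so a biological explanation by genotype was not tested separately.

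St6galnac2 was lower in DKO kidney although it was not a target in that line, and in other tissues of the line it differed, without a call, by -0.59 ± 0.22 (testes) and, in the other direction, 1.41 ± 0.83 (mammary gland), while the only WT array that matches thymus read 6.07, below all 5 DKO thymus arrays (6.80 to 7.43). The WT males N3740 and N3738 alone do not account for it, since without them the difference was -0.55. DNA flanking the targeted B4galnt2 gene, on the same chromosome as St6galnac2, may carry a different sequence in DKO mice. The 82 measured genes on chromosome 11 had a median size of the moderated statistic of 1.13, above that of 67.9% of 10000 random gene sets, so this cannot be told apart from chance with the genes measured, and their distance from B4galnt2 was not tested. Chance could not be excluded either, as 5 of 100 splits of the 9 animals called at least as many probe sets as the 1 of the real split, and a highest other of 202 points to a structure of the samples.

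In WT kidney N9686, the only female of 4 animals, lay far from the 3 males for 10 genes, with Ugt8a at 6.21 (males from 9.30 to 9.68), Chst7 at 5.36, Chst11 at 6.65, Galns at 8.30, Angptl7 at 5.31, Timd2 at 4.905 and Sdc2 at 8.30 below them, and Igf2 at 10.24, Lum at 5.97 and Tenm4 at 5.95 above. The gap exceeded Dixon's critical value in 10 of 83 tested pairs of gene and group, and the 1 in 20 that chance gives does not apply, since these genes were named for their difference between the sexes in a fit that includes N9686. The DKO effect differed between tissues for 33 probe sets, among them Igf2r (adjusted p = 0.0028), Ugt1a6b (0.0249), Klrd1 (0.035), Il12a (0.0404), Ccl5 (0.0479) and Cxcr3 (0.049). Among the 283 probe sets without a symbol, which were tested only in the alternative with all probe sets of the array, 1 was called for the St6galnac2 KO mean over 4 tissues, 11 for the DKO mean over 4 tissues and 8 for St6galnac2 KO against C57 brain, besides 5 for the DKO effect differing between tissues, 5 for sex in kidney and 5 to 30 in each tissue comparison.

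Splits of the samples into groups of the same sizes were counted together with the real split. The share with as many calls was under 0.05 for the tissues thyroid (83 called, highest other 31, 1 of 100 splits as large), lymph node (142, 41, 1 of 100), brain (97, 81, 1 of 100), intestine (48, 107, 3 of 100), thymus (105, 173, 2 of 100), testes (270, 23, 1 of 100) and kidney (198, 6, 1 of 100), and for sex in kidney (87, 1, 1 of 84). The tissue splits shuffled labels over arrays of different organs. A low share there says only that the tissue labels carry information, and chance for single genes was not tested. Higher counts under other splits in intestine and thymus point to a structure of the samples. Chance could not be excluded for the DKO mean over 4 tissues (8, 363, 8 of 100), the DKO effect differing between tissues (33, 378, 5 of 100) and sex in mammary gland (3, 25, 4 of 35). In kidney, in the mean and in the difference between tissues the highest other split put N3738 and N3740 with females N5891, N5892 and N9686, and counts several times the real count point to a structure of the samples. With 10 splits, too few for a share under 0.05, the real and highest other counts were 3 and 2 in DKO testes (1 as large) and, with 10 of 10 as large, 0 and 2 in St6galnac2 KO thyroid, 0 and 11 in lymph node, 0 and 263 in brain, 0 and 42 for the mean over 4 tissues, 0 and 312 for its difference between tissues, 0 and 0 for KO against C57 in brain, 0 and 16 for WT against C57 in brain and 0 and 0 for WT against C57 in intestine. The counts of 263, 312 and 42 came from the same split, with 9093, 9094 and 9099 together. With sex in the fit it sets 9099 against the other males, so its arrays that stand apart may cause these counts. Where the real count is 0 every split is as large, so these shares, and the 56 of 56 in DKO thymus (0 by limma, 202 unadjusted, highest other 167), say nothing about chance. Comparisons with a group under 3 animals were not split.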

How the results depend on the processing

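The tests without the 4 arrays that stand apart and without animals N3740 and N3738 were chosen only after the result was seen, and the others before.

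Where a setting and a result are given with no further remark, the cause was not tested. With all groups of the line in a single fit, called probe sets numbered 1 in St6galnac2 KO lymph node, 267 in DKO thymus (126 higher, 141 lower), 1 in DKO testes, 34 in DKO mammary gland and 0 in DKO kidney, and B4galnt1 was called in thymus at -2.46. With all probe sets of the array 1 was called for the St6galnac2 mean and 11 for KO against C57 brain. The DKO mean had 34 (7 higher, 27 lower). With animals of neighbouring numbers as a block 1 was called in St6galnac2 KO thyroid, and St6galnac2 in KO intestine was at -0.054. The block changed no other count in that line. With the first brain array of 9099 alone brain tissue had 27 calls, and with the second alone 215, with St6galnac2 at -0.20 and the intestinal epithelium list at -0.17 in WT against C57 brain. An estimated correlation left 0 of the 56 list calls that had one. After centring on the array median the DKO mean had 4 calls and the difference between tissues 10. In males only, which have fewer animals, St6galnac2 KO thyroid had 2 calls and DKO kidney 0. Without the animal block the DKO mean had 49 calls and the difference between tissues 13. A second quantile normalization gave 1 call in DKO mammary gland, where B4galnt2 was at 0.030, 5 for the DKO mean, 17 for the difference between tissues and 0 for KO against C57 intestine. With the animal as a block in tissue comparisons brain had 53 calls and intestine 22, and the genes that lost theirs are named above. A trended and robust prior variance, and the exclusion of dim probe sets, each left 5 calls for the DKO mean.

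Without N3740 and N3738 DKO kidney had 0 calls, the DKO mean 0 (78 unadjusted) with B4galnt1 at 0.15, and the difference between tissues 2. Without the 4 arrays St6galnac2 in KO intestine was at -0.054, its mean over 4 tissues at -0.012 and its difference in WT against C57 brain at -0.20. The connective tissue list in DKO thymus was at 0.19 with a test direction that reversed, the intestinal epithelium list in WT against C57 brain at -0.17 and the neural list in WT against C57 intestine at -0.24. The DKO mean had 5 calls, the difference between tissues 6, WT against C57 intestine 1, thyroid 164, brain 332 and intestine 275, and Prol1 in thymus tissue reversed to -2.66. The calls of the intestinal list in KO brain and in WT against C57 brain, and of the neural list in WT against C57 intestine, thus rested on those arrays, while both lists kept their calls in the tissue comparisons.

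Leaving out each animal in turn gave these ranges, with the animal left out in brackets. Within a tissue of the St6galnac2 line, KO against WT without 9094 equals that without 9093. Counts in the St6galnac2 line ran from 0 (9362) to 2 (9094) in KO thyroid, 0 to 1 (9361) for the mean over 4 tissues, 0 to 1 (9099) for WT against C57 intestine and 0 (GDWTF1) to 2 (GDWTF2) for KO against C57 intestine. In tissues they ran from 2 to 104 in thyroid, 28 to 161 in lymph node, 3 to 282 in brain and 3 to 258 in intestine, each time without 9362 and without 9099. St6galnac2 ran from -0.50 (9094) to 0.0076 (9362) in KO lymph node, -0.054 (9099) to 1.48 (9362) in KO intestine, -0.032 (9099) to 0.24 (9362) for the mean and -0.20 (9099) to 0.51 (9362) in WT against C57 brain. The intestinal epithelium list ran from -0.19 (9099) to 1.41 (9094) in WT against C57 brain, and the neural list from -0.24 (9099) to 2.12 (9362) in WT against C57 intestine. Counts in the other line ran from 0 to 376 (N9700) in DKO thymus, 0 to 205 (N9700) in testes, 0 to 2 (N9686) in mammary gland, 0 (N9686) to 2 (N9700) in kidney, 1 (N3738) to 317 (N9700) for the mean, and 0 (N3738) to 363 (N9700) for the difference between tissues. They ran from 52 (N3738) to 153 (N9700) in thymus tissue, 107 (N3738) to 198 (N9700) in mammary tissue, 44 (N5892) to 111 (N5893) for sex in kidney and 0 (N3738) to 14 (N5895) for sex in mammary gland. B4galnt1 ran from -3.51 (N9700) to -1.87 (N3738) in thymus, -0.47 (N9700) to -0.18 (N3738) in testes and -0.83 (N9700) to -0.28 (N3738) for the mean. B4galnt2 ran from -2.45 (N9700) to -1.06 (N3740) in thymus, -1.79 (N3738) to 1.42 (N9686) in mammary gland, -0.056 (N5895) to 0.10 (N3740) in kidney and -0.81 (N3738) to 0.0028 (N9686) for the mean.

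Counts stayed within 1.5 times in 23 of 26 with all probe sets, 24 with centring, 22 with quantile normalization, 25 with the trended prior, 25 without dim probe sets, all 7 without a sex covariate and 92 of 150 with an animal left out. Comparisons with no call in either setting are included, so part of these shares could hardly fail. The 7 without a sex covariate had at most 1 call in the main fit. Named genes kept their direction and their side of the threshold in 245 cases after centring, with 6 weaker, and in 1331 with an animal left out, with 131 weaker, 43 stronger and 13 reversed. Males only was not run in intestine and mammary gland, where a group would hold a single male. An offset before logarithms was not run because the values are already log2. Where leaving out arrays leaves a group with a single animal, that animal is assumed to vary like the other groups. This was so in WT thymus and, without N3740 and N3738, in WT testes. The percentile 25 of all values on the arrays was 4.211, and differences of genes near it may be compressed by background.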

Other observations

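The tests of distance between arrays were chosen only after the result was seen.

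The tissues differ in the enzymes that the knockouts remove. B4galnt2 was highest in C57 small intestine at 11.77 and at 3.57 in C57 brain, and B4galnt1 read 9.28 in WT intestine and 5.61 in WT thyroid of the St6galnac2 line. The 9.28 includes the intestine array of 9099 that resembles brain (7.85), and the other 2 arrays read 10.18 and 9.80. In WT testes the polypeptide GalNAc transferases (19 measured, median 0.07, adjusted p = 0.872) had 2 higher, 3 lower and 14 not called, 4 adjusted over the list alone, with Galntl5 (7.53), Galnt4 (-2.55), Galnt2 (-1.69) and Galnt11 (-1.76) first. Of the 56 growth factors and receptors 0 were higher, 14 lower and 42 not called in testes, 14 adjusted over the list alone (median -0.29, adjusted p = 0.727), with Fgf1 (-3.49), Vegfa (-4.81), Tgfbr2 (-3.09) and Vegfb (-2.26) first. In female kidney the 19 sialyltransferases had 3 higher, 0 lower and 16 not called, 3 adjusted over the list alone (median 0.04, adjusted p = 0.825), with St3gal2 (0.51), St3gal6 (0.52) and St6gal1 (0.36).

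In lymph node the list of interleukins and receptors was higher (45 measured, median 0.47, adjusted p = 6.60e-05, adjusted p = 0.268 with an estimated correlation), with 10 higher, 0 lower, 35 not called, 10 adjusted over the list alone and Il1r1 (1.67), Il2rg (3.88), Il10ra (1.95) and Il7r (3.93) first. In brain the 10 markers of macrophages and myeloid cells were lower (median -1.36, adjusted p = 0.00113, adjusted p = 0.361 with an estimated correlation), with 0 higher, 3 lower, 7 not called and 4 adjusted over the list alone, Clec10a (-2.07), Mrc1 (-2.30) and Mgl2 (-2.25).

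The testes and kidney arrays of WT males N3740 and N3738 lay close together. In testes their root mean square distance was 0.189 on the log2 scale, against 0.339 to 0.412 to the other males and 0.241 to 0.286 among those. In kidney it was 0.19, against 0.279 to 0.372 and 0.22 to 0.302.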
